A study of Mus musculus with 6 samples.

How the data were processed

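RNA from mouse muscle was sequenced in 6 libraries, 3 from control animals and 3 from animals labelled as having their Igf2 gene removed in muscle. Per the labels, the animals were on a C57BL/6 background. Both alleles of Igf2 carried loxP sites around exon 2 (Igf2f/f). The Igf2 conditional knockouts (Igf2 cKO) also carried Cre recombinase under the muscle creatine kinase promoter (Mck-Cre), which is active in striated muscle fibres, and controls were littermates without Cre. The labels do not name the muscle, the age or the sex. Groups and replicate numbers were taken from the sample titles.

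Per the labels, the RNA was isolated with Trizol and then sequenced and analysed by a commercial service on an Illumina NovaSeq instrument. The aligner, the counting tool and its strand setting, the genome build and the annotation are not given in the sources used here. Per the file headers, the deposited table holds a raw count and an FPKM for each gene and library, and the values in the count columns are whole numbers with a different total in each library. The authors' FPKM divides each count by the listed gene length and by 1 library size per library, which lies between 0.942 and 1.04 times the column total of the counts, so a composition factor had been applied. The authors' log2 fold change, with a p-value and an adjusted p-value, is also deposited for 3 comparisons, each of 1 Igf2 cKO library against the control library of the same number. How these p-values were obtained from 1 library against 1 is not given in the sources used here. Another 6 columns of per-sample values carry names that do not match the sample titles and were not used here. The table lists 54532 genes. Of these, 54495 gene identifiers occur in the GENCODE release M21 annotation, and 53585 of them (98.3%) have the same start and end there, so coordinates are given as in the table and match the mouse build GRCm38.

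Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with genotype as the model's single term, TMM factors, the default low-count filter (filterByExpr), and Benjamini-Hochberg adjustment over the 14867 genes tested. A gene was called at an adjusted p under 0.05, with no limit on the fold change. Log2 fold changes are Igf2 cKO over control, with the standard error derived from the F statistic and 95% intervals. CPM values are counts scaled by the TMM library sizes. All statistics other than those credited to the authors' deposited table were computed this way.

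The comparisons and 42 gene lists (pathways, fibre types and markers of other cell types in muscle) were fixed before the data were examined. Each list was tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 42 lists. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and makes no comparison with other genes, were alternatives. The result of every list is given. Shares of counts were compared with two-sided exact permutation tests, which with 3 against 3 libraries cannot go below p = 0.1. Intervals of single-library shares are exact Clopper-Pearson 95% intervals and cover counting error only.

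Genes named in the text followed a rule set before the data were examined. It took Igf2, its neighbours H19, Ins2 and Igf2os, and Igf1, Igf1r and Igf2r. It took up to 12 genes per direction with the largest fold change among calls with a mean CPM of at least 1 and no overlap between the groups, made up to 12 with the smallest p where fewer passed. From each list it took up to 4 called members with the largest fold change, or the 2 members with the smallest p where fewer than 2 were called. The 8 most abundant genes, the myosin heavy chains and the 13 protein genes of mitochondrial DNA completed it. Genes named outside this rule are said to be so, and a few results that the rule would take are not reported here.

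Alternatives were other size factors (DESeq2-type and upper quartile), library sizes without mitochondrial DNA genes, no low-count filter, a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, an adjusted p under 0.1, the rule the series states (unadjusted p under 0.05 and an absolute log2 fold change over 1), and leaving out each library in turn. FPKM served only as an alternative for the myosin shares. A fit with a slow fibre score (mean log2 CPM of the tested slow fibre list) as a covariate was added after the data had been seen. None of these scalings moved the median log2 fold change of all genes by over 0.1.

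The fit was tested on simulated counts for the 14867 genes, drawn from the real means, library sizes and dispersions, with 200 genes changed. It called 13.4% of the 67 genes changed 1.5-fold, 71.6% of the 67 changed 2-fold and 100% of the 66 changed 4-fold, all in the right direction. Of its 142 calls, 19 were genes that had not been changed, which is above the nominal 5% and a limit on the calls given here. In a second simulation of this kind, only the list of glucocorticoid targets was raised, by 1.5-fold. It ranked first, and 0 lists without its genes were called by camera at the preset correlation. Each gene was drawn independently of the others, so this does not test the preset correlation on genes that vary together.

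Total counts were between 16184371 and 17905203 per library. No 2 libraries of a group agreed within sampling noise, with chi-square values per degree of freedom between 15.6 and 84.6. Tables and exact tests used Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.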

Results

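The series compared muscle of 3 control (Igf2f/f) mice with muscle of 3 mice labelled as lacking Igf2 in muscle fibres (Igf2 cKO), each sequenced as 1 library. Igf2 encodes insulin-like growth factor 2, a fetal growth factor, and the title of the series ties its loss to sarcopenia, the decline of muscle mass and function. Total counts of control replicates 1 to 3 were 17905203, 17820729 and 16335647. Those of Igf2 cKO replicates 1 to 3 were 17503334, 16184371 and 16889674. Between 20791 and 21401 genes had at least 1 count in a library. The 8 most abundant genes were Acta1, Myh4, mt-Co1, Atp2a1, Tpm1, Aldoa, Ckm and mt-Cytb. Together they took between 15.6% and 18.9% of the counts of a library, with Acta1, skeletal muscle actin, at a mean of 3.58%.

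The targeted gene was barely detected in muscle of either group. Igf2 (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816, minus strand, GRCm38) had 60, 43 and 39 counts in control replicates 1 to 3 and 33, 37 and 42 in Igf2 cKO replicates 1 to 3. The means were 47.3 ± 11.2 (SD, n = 3) and 37.3 ± 4.51 counts (SD, n = 3). The log2 fold change was -0.31 ± 0.25 (SE, 95% interval -0.89 to 0.26), with an adjusted p of 0.751 by edgeR, so no difference was detectable. In the authors' deposited table Igf2 had log2 fold changes of -0.81, -0.07 and -0.04 in the 3 comparisons of single libraries, with an adjusted p of 1.0 in each. The deposited count is summed over the gene and does not separate the floxed exon from the others, and it includes cells without Cre, so it does not check the genotype labels. Igf2os, annotated on the opposite strand and overlapping Igf2, had between 1 and 11 counts, and without a stated strand setting its reads cannot be separated from those of Igf2.

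Neighbours and receptors of Igf2 did not pass the test either. H19, the maternally expressed noncoding RNA beside Igf2, was abundant, at 827.5, 685.7 and 787 CPM in control replicates 1 to 3. In Igf2 cKO replicates 1 to 3 it stood at 562.9, 1643 and 693.4 CPM. Its log2 fold change was 0.33 ± 0.36 (SE, adjusted p = 0.83) and became -0.29 without Igf2 cKO replicate 2. Ins2 had at most 2 counts in a library and was not tested. Igf1, the related growth factor, had a log2 fold change of 0.42 ± 0.20 (SE, adjusted p = 0.533). The receptors Igf1r (-0.34 ± 0.13, adjusted p = 0.42) and Igf2r (-0.07 ± 0.09, adjusted p = 0.858) also missed the threshold. In the list of IGF signalling genes, 0 of 21 tested members were called by edgeR, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05 in edgeR. These were Foxo1, a transcription factor restrained by insulin signalling, at a log2 fold change of 0.28 (adjusted p = 0.384), and Igf1r. The list median was 0.05 (camera adjusted p = 0.408). The imprinted gene network had a median of 0.04 over 19 tested members (camera adjusted p = 0.55), with Impact at 0.24 (adjusted p = 0.483) and Ndn at 0.36 (adjusted p = 0.548), both short of the threshold.

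Ddit4, Slc25a25 and Ppp1r3c were higher and Socs1 and Pfkfb3 lower in Igf2 cKO muscle. Ddit4 (REDD1, an inhibitor of mTORC1 induced by glucocorticoids and stress) was at 29.9 ± 2.21 CPM in controls and 231 ± 9.11 CPM in Igf2 cKO muscle (SD, n = 3 each), a log2 fold change of 2.95 ± 0.11 (SE, adjusted p = 1.62e-05). Slc25a25, a calcium-regulated ATP-Mg/phosphate carrier of mitochondria, rose from 30.5 ± 13.3 to 314 ± 113 CPM (log2 fold change 3.36 ± 0.37, adjusted p = 0.0118). Ppp1r3c, which targets protein phosphatase 1 to glycogen, rose from 81.0 ± 9.87 to 572 ± 165 CPM (2.82 ± 0.22, adjusted p = 0.00305). Socs1, a feedback inhibitor of cytokine signalling, fell from 59.4 ± 32.9 to 4.78 ± 2.90 CPM (-3.64 ± 0.54, adjusted p = 0.0475), and Pfkfb3, which makes the glycolytic activator fructose 2,6-bisphosphate, fell from 845 ± 168 to 232 ± 49.8 CPM (-1.86 ± 0.21, adjusted p = 0.0118).

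In all, 37 of 14867 genes were called by edgeR with Benjamini-Hochberg adjustment, 27 higher and 10 lower in Igf2 cKO muscle, each with the 3 libraries of one group apart from the 3 of the other. Over all tested genes 15.5% had such groups, against 10% by chance. At an unadjusted p under 0.05 there were 1477 genes, where 743 would be due by chance. Other splits of the 6 libraries, 3 against 3 with the genotypes mixed, gave between 367 and 1134 such genes. The rule the series states, an unadjusted p under 0.05 with an absolute log2 fold change over 1, took 235 genes, 117 higher and 118 lower. DESeq2 called 214 genes, which include the 37. The count of calls was 8, 15 and 13 without control replicates 1, 2 and 3, and 68 and 17 without Igf2 cKO replicates 2 and 3, and 7 of the 37 genes were called with any 1 library left out (Ddit4, Arrdc2, Ppp1r3c, Fgfr3 and Slc43a1, with Noct and Arrdc3 named after their values were seen).

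Among the other genes that rose most, Arrdc2, an alpha-arrestin gene, had a log2 fold change of 2.84 ± 0.17 (SE, adjusted p = 0.000522, chromosome 8, 70835129 to 70839720). Lrrc30, a leucine-rich repeat gene, rose by 1.95 ± 0.20 (adjusted p = 0.00926) and the fibroblast growth factor receptor gene Fgfr3 by 1.61 ± 0.16 (adjusted p = 0.00718). Fam107a had a log2 fold change of 1.87 (adjusted p = 0.00718), and the noncoding RNA E230001N04Rik rose by 2.25 from a control mean of 0.621 ± 0.0534 CPM (adjusted p = 0.0274). Nr4a3, an immediate early nuclear receptor, rose by 1.60 (adjusted p = 0.0179), Angptl7, a secreted angiopoietin-like protein, by 1.58 (adjusted p = 0.0413), and Csrnp1 by 1.39 (adjusted p = 0.031). Tsc22d3 (GILZ, a classical glucocorticoid-induced gene) rose from 197 ± 35.1 to 559 ± 108 CPM (SD, n = 3 each, adjusted p = 0.0179). E230001N04Rik was not called in any of the 6 fits with a library left out. The remaining 10 higher genes outside the naming rule were Arrdc3, Errfi1, Tob2, Banp, Cebpb, Noct, Glul, Sox17, Dysf and Dusp8, named after their values were seen, with log2 fold changes between 0.65 (Dusp8) and 1.38 (Arrdc3).

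**Figure D1:**
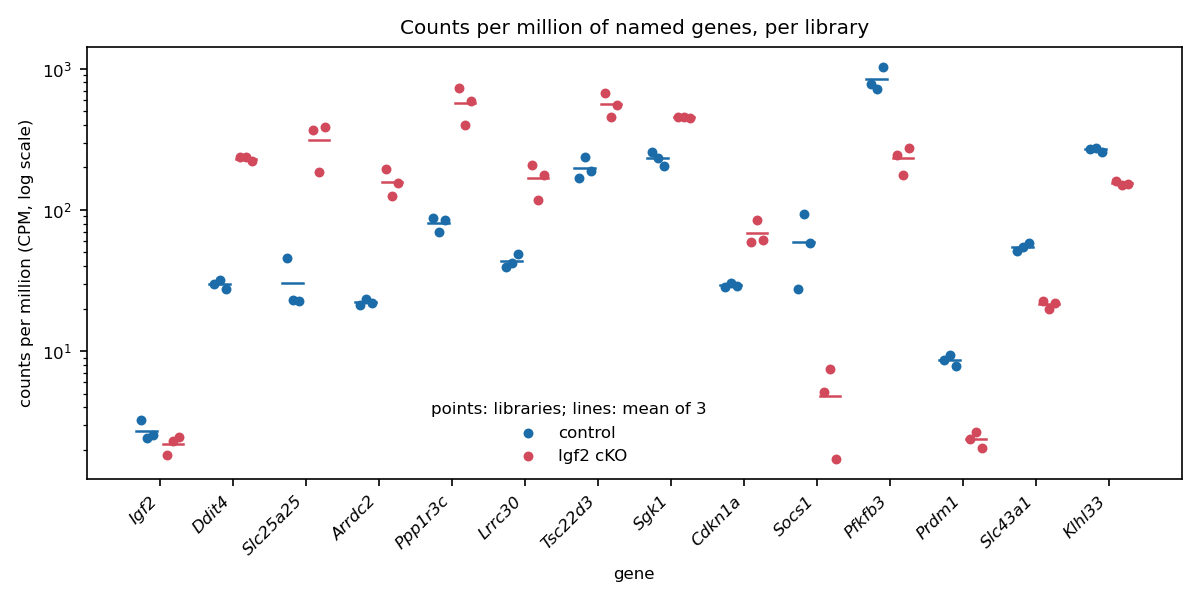
CPM on a log axis for Igf2 and 13 called genes, with 1 point per library, colour for the group and a line for the mean of 3 libraries. The libraries of the groups overlap for Igf2 and are apart for the other genes, as for Ddit4 with means of 29.9 CPM in control and 231 CPM in Igf2 cKO muscle.

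Of the lower genes, Prdm1 (BLIMP1, a transcriptional repressor) had a log2 fold change of -1.86 ± 0.19 (SE, adjusted p = 0.00793), Slc43a1 (LAT3, a transporter of branched-chain amino acids) of -1.34 ± 0.10 (adjusted p = 0.00217) and Bcl6b of -1.22 ± 0.14 (adjusted p = 0.0156). Fam84b (-1.17), Ccrl2 (-0.94), Dusp10, a phosphatase of stress-activated kinases (-0.89), Klhl33 (-0.79) and Fam214a (-0.68) were also lower, with adjusted p between 0.0114 and 0.0245. Ier5l (-0.85, adjusted p = 0.0529) and 1190002N15Rik (-0.71, adjusted p = 0.0517) came next and failed the correction. Socs1 kept its call in 1 of the 6 fits with a library left out, and its adjusted p over all alternatives ran from 4.85e-09 to 0.164.

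Of the 37 called genes, 8 passed the adjusted p under 0.05 of the authors' deposited table in all 3 comparisons of single libraries and 19 in at least 1. At the authors' adjusted p under 0.05, the deposited table calls 95, 72 and 149 genes in the comparisons of replicates 1, 2 and 3. By the authors' deposited table, higher values in all 3 comparisons were called for 6 genes, and 0.000614 would be due for independent lists. They are Arrdc2, Ddit4, Fam107a, Slc25a25, Ppp1r3c and Gm21887, the last of which was not called by edgeR and was named after its values were seen. The 3 genes lower in all 3 comparisons of the authors' deposited table were Pfkfb3, Socs1 and Prdm1, where 0.000137 would be due. Both analyses use the same 6 libraries, so one is not a separate test of the other.

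Glucocorticoid targets moved up as a list. Of 15 tested members, 5 rose over all genes tested (9 adjusted over the list alone), and the median log2 fold change was 0.90. The count of called members was 1 without control replicate 1, 2 or 3, 2 without Igf2 cKO replicate 3, 8 with DESeq2 and 9 with no filter on low counts, while the median lay between 0.83 and 0.97 with any 1 library left out. Beside Ddit4 and Tsc22d3, the members called over all 6 libraries were Cdkn1a, which encodes the cell cycle inhibitor p21 (1.23 ± 0.15, adjusted p = 0.0156), Sgk1, the serum- and glucocorticoid-regulated kinase (0.97 ± 0.12, adjusted p = 0.0179), and Glul, glutamine synthetase (0.88 ± 0.12, adjusted p = 0.0318), which the naming rule did not take. Camera gave an adjusted p of 3.94e-11, and the adjusted p = 0.285 with an estimated correlation, while fry gave 0.00538. Not every member moved, with Klf9 at 0.01 (adjusted p = 0.984), Fkbp5 at 0.37 (adjusted p = 0.549) and Pdk4 at -1.13 (adjusted p = 0.637), which were named after their values were seen. The mean log2 CPM of the list was 5.25, 5.47 and 5.20 in control replicates 1 to 3. In Igf2 cKO replicates 1 to 3 it was 5.95, 6.18 and 6.06.

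The list of muscle atrophy and ubiquitin ligase genes, which bears on sarcopenia, did not pass camera (adjusted p = 0.25, median 0.04 over 23 tested members). Fry gave an adjusted p of 0.018 in the higher direction. Ddit4 was its 1 called member, and 6 passed adjusted over the list alone. The 3 higher ones, Ddit4, Mt1 and Klf15 (0.55), are also in the glucocorticoid list. The 3 lower ones were Fbxo32, Fbxo21 (-0.37) and Cblb (-0.48). Klf15, Fbxo21 and Cblb were named after their values were seen. Mt1, a metallothionein, was at 0.99 (adjusted p = 0.111). The ligase gene Fbxo32 (atrogin-1) had a log2 fold change of -0.99 ± 0.30 (adjusted p = 0.295) and Trim63 (MuRF1) of -0.09 ± 0.13 (adjusted p = 0.889), both named after their values were seen. For autophagy and mitophagy the median was 0.05 over 20 members (camera adjusted p = 0.911), with Ulk1 at -0.38 (adjusted p = 0.36) and Tfeb at 0.25 (adjusted p = 0.521). Both directions were seen in the senescence and cell cycle arrest list, where Cdkn1a rose, 5 of 15 members passed adjusted over the list alone (2 higher and 3 lower), and camera gave 0.609.

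Chaperone and stress-response lists were shifted up by smaller amounts by camera at the preset correlation. Neither passed fry (adjusted p = 0.401 for heat shock and 0.0965 for the integrated stress and unfolded protein response). Heat shock genes had a median of 0.31 over 15 tested members, of which 13 lay above 0. Camera gave an adjusted p of 5.77e-05, and the adjusted p = 0.723 with an estimated correlation. By edgeR 0 members were called over all genes (5 adjusted over the list alone, 6 at an unadjusted p under 0.05), while DESeq2 called 3 and limma-voom 0. Hsp90aa1 was at 0.59 (adjusted p = 0.192) and Dnaja1 at 0.43 (adjusted p = 0.208), both chaperone genes that fail the correction. The integrated stress and unfolded protein response list had a median of 0.30 over 21 members, with camera at an adjusted p of 0.000746, and the adjusted p = 0.62 with an estimated correlation. By edgeR 0 of its members were called (2 adjusted over the list alone, 9 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom). They were led by Atf3, a stress-induced transcription factor (1.41, adjusted p = 0.107), and Hspa5, the chaperone BiP of the endoplasmic reticulum (0.68, adjusted p = 0.112). In this list 16 members lay above 0 and 5 below. Chac1, named after its values were seen, was 1 of the 9 and lay at -1.53 (adjusted p = 0.498).

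Immediate early genes had a median of 0.39 over 22 members, with Nr4a3 as the 1 called gene over all genes (4 adjusted over the list alone, 3 higher and 1 lower). Camera gave an adjusted p of 0.0146, and the adjusted p = 0.95 with an estimated correlation, while fry gave 0.933. The call was lost without control replicate 1 (0.0872), without control replicate 3 (0.132) and without Igf2 cKO replicate 1 (0.368). In the circadian clock list Nfil3, a repressor of clock output genes, rose by 1.38 ± 0.20 (adjusted p = 0.0459). Per1, which is also a glucocorticoid target, was at 0.79 (adjusted p = 0.0584). With 6 of 18 members past the threshold adjusted over the list alone, 4 higher and 2 lower, camera gave 0.774.

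Cell cycle, interferon and red cell genes were lower as lists by camera at the preset correlation, but not by fry (adjusted p = 0.205, 0.205 and 0.0965). The proliferation list had a median of -0.94 over 18 tested members, with camera at an adjusted p of 4.15e-08, and the adjusted p = 0.62 with an estimated correlation. Its members had low counts. The cyclin gene Ccna2 was at -1.79 ± 0.36 (adjusted p = 0.141), with 3.4 CPM in controls, and the kinetochore gene Cenpf at -1.75 ± 0.42 (adjusted p = 0.201). By edgeR 0 members were called (7 adjusted over the list alone, 9 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom). Interferon response genes had a median of -0.29 over 26 members, with camera at 4.59e-06, and the adjusted p = 0.62 with an estimated correlation. In this list 0 members were called by edgeR, DESeq2 or limma-voom (6 lower adjusted over the list alone in edgeR, 9 at an unadjusted p under 0.05), with Oasl2 at -0.55 (adjusted p = 0.222) and Ifit1 at -0.50 (adjusted p = 0.263). Immune cell lists also had medians below 0 but did not pass camera. These were T, B and NK cells (-0.81), macrophages (-0.22), neutrophils (-0.34) and class II antigen presentation (-0.26). Erythroid markers, which track blood in the sample, had a median of -0.55 over 7 members, with camera at 3.02e-05, and the adjusted p = 0.62 with an estimated correlation. The globin genes Hbb-bs (-0.65, adjusted p = 0.194) and Hba-a1 (-0.55, adjusted p = 0.201) led them, and near-identical globin copies can share reads. By edgeR 0 erythroid members were called (6 lower adjusted over the list alone, all 6 at an unadjusted p under 0.05, 3 by DESeq2, 0 by limma-voom).

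**Figure D2:**
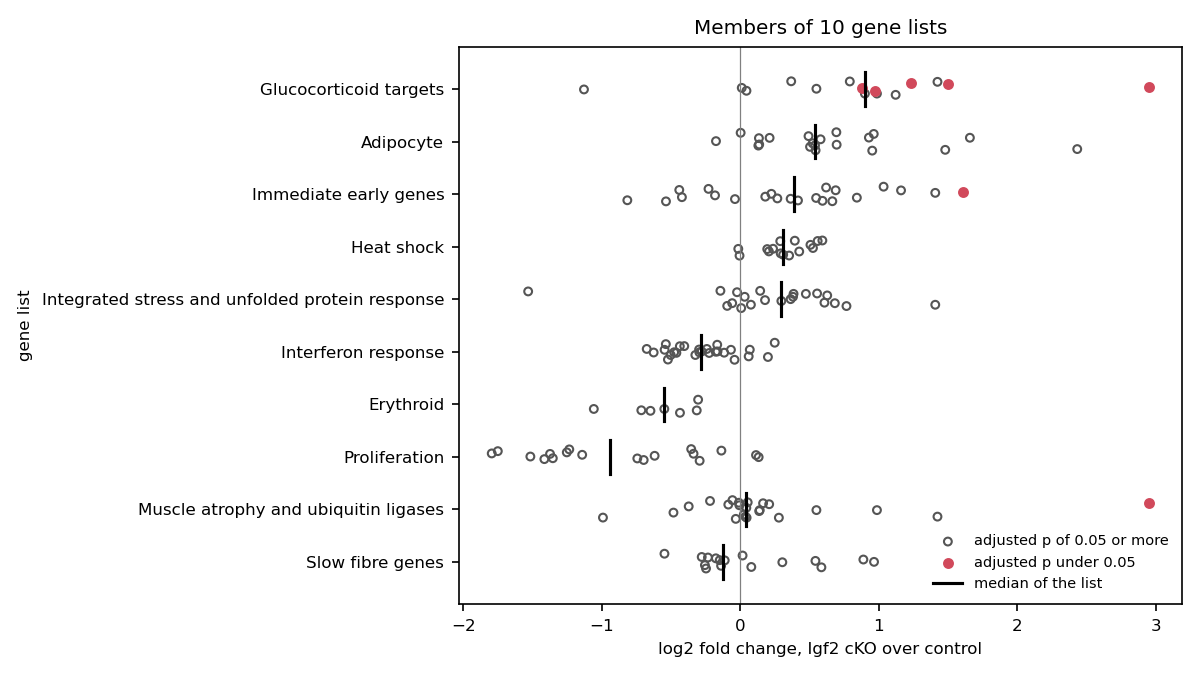
Log2 fold changes (Igf2 cKO over control, x axis) of the tested members of 10 gene lists, the 8 past camera's threshold and 2 others, with 1 point per gene, filled where the adjusted p was under 0.05, and a line at the list median. Glucocorticoid targets have the highest median, 0.90, and proliferation genes the lowest, -0.94.

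Markers of other cells in muscle were compared in the same way. Adipocyte markers had a median of 0.54 over 20 members (camera adjusted p = 0.0423, and the adjusted p = 0.95 with an estimated correlation, fry 0.933). Thrsp was at 0.96 (adjusted p = 0.19) and Pck1 at 2.43 (adjusted p = 0.308). The mean log2 CPM of the adipocyte list was 6.66 in Igf2 cKO replicate 3, against 5.43 and 4.88 in the other Igf2 cKO libraries and at most 5.59 in controls. The adipocyte call was lost without Igf2 cKO replicate 3 (0.85) and without control replicate 3 (0.39). In the adipocyte list 0 members were called by edgeR (1 adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). T, B and NK cell markers had a median of -0.81 over 6 tested members (camera adjusted p = 0.0536, fry 0.018), at low counts, with Jchain at -1.22 (adjusted p = 0.384) and Trac at -1.69 (adjusted p = 0.477). Schwann cell and nerve markers had a median of 0.52 (camera adjusted p = 0.0536), with Egr2 at 0.84 (adjusted p = 0.464) and Mag at 0.64 (adjusted p = 0.631).

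Other cell markers lay further from the threshold. The medians were -0.22 for macrophages (camera adjusted p = 0.346, Ctss at -0.48 and Itgam at -0.60), -0.34 for neutrophils (0.537, Csf3r at -0.59 and S100a9 at -0.34) and -0.19 for fibroblasts and fibro-adipogenic progenitors (0.234, Dpp4 at -0.52 and Pi16 at -0.49). They were -0.04 for endothelium (0.467, Cldn5 at -0.61 and Egfl7 at -0.26), 0.05 for smooth muscle and pericytes (0.143, Acta2 at 0.80 and Cnn1 at 1.09), 0.27 for tenocytes (0.164, Col11a1 at 0.33 and Mkx at 0.40) and -0.17 for skin (0.609, Sbsn at -0.24 and Krt10 at -0.10). None of these 14 genes passed edgeR's adjustment, the lowest adjusted p being 0.0956 for Acta2. Without control replicate 3, which had the lowest means of macrophage and fibroblast markers among controls (3.93 and 6.74 on the log2 CPM scale), both lists were lower by camera, at 2.05e-06 and 0.00033. Sex-linked genes (median -0.01, camera 0.911, with Uty at -0.07 and Kdm5d at 0.02) did not separate the groups. The Y-linked gene Ddx3y had 1577 to 2011 counts per library and Xist, expressed from the inactive X of females, 0 to 3. All 6 libraries thus read as male. These 2 genes were named outside the rule.

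Fibre type genes set 1 library apart. Myh4, the fast IIb myosin, made up 67.8% of the counts of Myh1, Myh2, Myh4 and Myh7 in Igf2 cKO replicate 2 (95% exact interval 67.7 to 67.9), against 92.1% and 88.0% in Igf2 cKO replicates 1 and 3 and 90.1 ± 2.01% in controls (SD, n = 3). Myh7, the slow myosin, took 1.61% (1.57 to 1.65) in Igf2 cKO replicate 2, 0.122% (0.114 to 0.131) in replicate 1 and 0.163% (0.152 to 0.174) in replicate 3, against 0.595 ± 0.182% in controls. The group means of the Myh7 share differed by 0.0353 percentage points, with p = 1.0 in the exact permutation test, where 3 against 3 cannot go below 0.1. Without Igf2 cKO replicate 2 the difference was -0.453 percentage points. The exact tests of Myh1 (p = 0.3), Myh2 (p = 0.7) and Myh4 (p = 0.7) gave an adjusted value of 1.0 each. Myosin genes are similar in sequence, so the counting could have split reads between them. The developmental myosins Myh3 and Myh8 had means of 31.3 ± 9.29 and 169 ± 56.6 counts in controls and 30.7 ± 12.5 and 117 ± 72.1 counts in Igf2 cKO muscle (SD, n = 3).

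**Figure D3:**
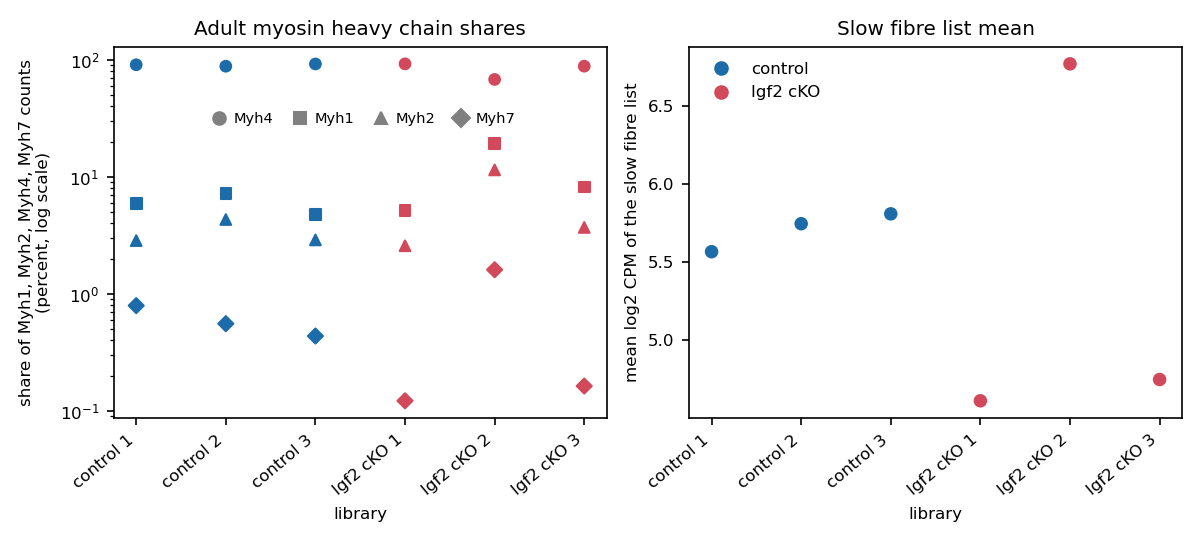
Left, shares of the 4 adult myosin heavy chain genes in their summed counts (percent, log axis) for each library. Right, mean log2 CPM of the slow fibre list per library, 6.77 in Igf2 cKO replicate 2, 4.61 and 4.75 in the other Igf2 cKO libraries, and 5.57 to 5.81 in controls.

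The slow fibre list did not pass over all 6 libraries (median -0.12 over 16 members, camera adjusted p = 0.346), with Csrp3 at 0.97 (adjusted p = 0.426) and Myl6b at -0.28 (adjusted p = 0.692). Without Igf2 cKO replicate 2 its median was -0.91 and camera gave 1.98e-12. The fatty acid uptake and oxidation list went from a median of -0.02 (adjusted p = 0.0828) to -0.36 (6.24e-09) in the same way. Nuclear oxidative phosphorylation genes went from -0.02 (0.911) to -0.17 (0.000124) and the tricarboxylic acid cycle from 0.00 (0.774) to -0.17 (0.00482). Each library was left out in turn by plan. The slow fibre and tricarboxylic acid cycle lists were called only without Igf2 cKO replicate 2, while fatty acid genes (0.00382) and nuclear oxidative phosphorylation (0.00923) were also lower without control replicate 1. Ucp3 (-0.93, adjusted p = 0.352) had the smallest p in the fatty acid list, Ndufa1 (0.22, 0.807) in oxidative phosphorylation, and Cs (-0.12, 0.872) and Suclg1 (-0.09, 0.886) in the cycle, and all 4 failed the correction. Counts on the 13 protein genes of mitochondrial DNA were 7.22 ± 1.05% of the total in controls and 7.41 ± 2.72% in Igf2 cKO muscle (SD, n = 3, two-sided exact permutation p = 0.9), with 10.2% in Igf2 cKO replicate 2. As a list they had a median of 0.06 (camera adjusted p = 0.902), with mt-Nd4l at 0.84 and mt-Atp8 at 0.96 (adjusted p = 0.752 each).

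The remaining muscle lists did not pass camera. Fast fibre genes had a median of -0.03 (adjusted p = 0.164, Myh4 at -0.54 and Mybpc2 at -0.39), and embryonic and neonatal contractile genes of -0.15 (0.456), with Actc1, cardiac actin, at -1.44 ± 0.31 (adjusted p = 0.162) and Myl4 at 0.46 (adjusted p = 0.691). Neuromuscular junction genes had a median of 0.11 (0.408, Dok7 at 0.35 and Ncam1 at 0.37). Satellite cell and myogenesis genes had a median of 0.13 (0.143), with the fusion gene Mymk at -2.01 ± 0.43 (adjusted p = 0.162) and Sdc4 at 0.63 (adjusted p = 0.169), and 3 members passed adjusted over the list alone, 2 higher and 1 lower. Medians were 0.02 for mitochondrial biogenesis and dynamics (0.913, Tfb2m at -0.27 and Ppara at 1.11), -0.03 for glycolysis and glycogen (0.609, Pgk1 at -0.34 and Hk2 at 0.28), 0.04 for calcium handling (0.609, Sln at 1.18 and Cacna1s at -0.22) and -0.06 for extracellular matrix (0.913, Serpinh1 at 0.57 and Ctgf at 0.78). They were 0.02 for the antioxidant response (0.479, Mt1 and Srxn1 at 0.37), -0.07 for cytosolic ribosomal proteins (0.143, Rplp0 at -0.21) and 0.05 for amino acid transport (0.913), in which Slc43a1 fell and Slc38a2 was at 0.43 (adjusted p = 0.263). For class II antigen presentation the median was -0.26 (0.0828, H2-Aa at -0.30 and H2-Eb1 at -0.26). The list of inflammatory cytokines and chemokines had a median of -0.20 (0.467), with Nfkbia, the inhibitor of NF-kB, higher (1.17 ± 0.13, adjusted p = 0.0118) and Socs3, a feedback inhibitor related to Socs1, at -3.16 ± 0.64 (adjusted p = 0.144). For 6 lists the median, the mean and the camera direction differ in sign, namely slow fibre, nuclear oxidative phosphorylation, mitochondrial biogenesis, senescence, circadian clock and amino acid transport, none of which passed.

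Several lists that were not called over all 6 libraries passed with 1 library left out, in 5 such fits for T, B and NK cell markers. Markers of T, B and NK cells were lower by camera without control replicate 1 (0.00944), control replicate 3 (0.0487), Igf2 cKO replicate 1 (0.00265), Igf2 cKO replicate 2 (0.0175) or Igf2 cKO replicate 3 (0.00428). Schwann cell and nerve markers were higher without control replicate 1 (0.00204), control replicate 3 (0.0487) or Igf2 cKO replicate 3 (2.61e-06), and tenocyte markers without Igf2 cKO replicate 2 (0.0407) or 3 (0.0406). Without control replicate 1, imprinted genes were higher (0.00736) and cytosolic ribosomal proteins lower (0.0155). Without control replicate 3, extracellular matrix (0.000221), class II antigen presentation (6.18e-05) and neutrophil markers (0.00706) were lower and neuromuscular junction genes higher (0.0471). Without Igf2 cKO replicate 1, fast fibre genes (0.0291) and cytosolic ribosomal proteins (0.017) were lower and mitochondrial DNA genes higher (0.0119), and without Igf2 cKO replicate 2 calcium handling genes were higher (0.0467). All of these are camera's adjusted p at the preset correlation.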

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

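The slow fibre covariate was chosen after the data had been seen; the other settings were planned. None of the 37 called genes changed sign in the 15 alternative fits. The counts of changed, higher and lower genes, 37, 27 and 10 as reported, were 282, 155 and 127 with no filter on low counts, 214, 113 and 101 with DESeq2, and 95, 62 and 33 with the slow fibre score as a covariate, each including all 37. The looser threshold of adjusted p under 0.1 gave 62, 39 and 23. The stated rule gave 235, 117 and 118. Leaving out 1 library gave 8 to 68 changed, 7 to 31 higher and 1 to 37 lower genes, with fewer samples in each fit. The cause of these and the other shifts was not tested. Other size factors, library sizes without mitochondrial genes, the CPM filter and limma-voom gave 34 to 39 calls. Lists past the threshold were 8 as reported, 0 with an estimated correlation (3 at an unadjusted p under 0.05), 3 with fry, and 8 to 15 leaving out 1 library. Those past fry were glucocorticoid targets (0.00538), muscle atrophy genes (0.018) and T, B and NK cell markers (0.018). The other lists past camera had fry adjusted p between 0.0965 and 0.933. The Igf2 log2 fold change lay between -0.41 and -0.17 in every setting and was never called. With the replicate number as a block, 35 genes were called, 25 higher and 10 lower, 27 of them among the 37, and 11 lists passed; the Igf2 value was -0.31, 3 glucocorticoid targets were called, and the adipocyte list was not called (0.0608). Deviations from the group means correlated at 0.163, 0.058 and -0.043 for equal numbers and between -0.183 and 0.122 for unequal numbers. Not every library correlated best with its own number. With 3 libraries per group, these values cannot tell whether the numbers pair the samples.

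Direction reversed for 8 named genes that were not called. Without Igf2 cKO replicate 2, H19 went to -0.287, mt-Nd4l to -0.412, mt-Atp8 to -0.105, Sbsn to 0.033, Krt10 to 0.077 and Kdm5d to -0.035. Without Igf2 cKO replicate 1, S100a9 went to 0.065 and Uty to 0.059. Without control replicates 1, 2 and 3 in turn, Kdm5d went to -0.045, Krt10 to 0.112 and Uty to 0.028. The other ends of the leave-one-out ranges were 0.608 for H19, 1.298 for mt-Nd4l, 1.461 for mt-Atp8, -0.719 for S100a9, -0.603 for Sbsn, -0.294 for Krt10, -0.156 for Uty and 0.083 for Kdm5d. These genes have small fold changes or high spread, and the cause was not tested. The Myh7 share difference was 0.034 percentage points with FPKM and -0.453 to 0.289 leaving out 1 library, and the mitochondrial share difference was -0.0233 without the 10 most abundant nuclear genes and -1.18 to 1.54. The largest of these moves exceed the control SD (0.182 and 1.05 points) and stay within the Igf2 cKO SD (0.845 and 2.72 points), to which Igf2 cKO replicate 2 adds. Depth limits Igf2os, at 1 to 11 counts, and Ins2, at no more than 2, which were not tested.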

Other observations

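Of the tests below, the Igf2 interval was chosen only after its result was seen, and the fit with the slow fibre score after the data had been seen. Errfi1, an inhibitor of the EGF receptor (1.28 ± 0.16 SE, adjusted p = 0.0179), Tob2, an antiproliferative protein (1.35 ± 0.20, adjusted p = 0.0459), and Arrdc3, an alpha-arrestin like Arrdc2 (1.38 ± 0.13, adjusted p = 0.00708), were higher in 3 of 3 Igf2 cKO libraries than in any control. Socs1 was lower, at 5.1, 7.5 and 1.7 CPM in Igf2 cKO replicates 1 to 3 against 27.3, 93.1 and 57.9 CPM in controls. Cebpb, a transcription factor of the acute phase and of adipocyte differentiation, rose by 1.16 ± 0.11 (adjusted p = 0.00718), and Noct, a deadenylase-like gene with daily rhythms, by 1.13 ± 0.10 (adjusted p = 0.007). Dysf, the membrane repair gene dysferlin, rose by 0.66 ± 0.10 (adjusted p = 0.047). These genes other than Socs1 were named after their values were seen.

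The glucocorticoid target list was higher in Igf2 cKO libraries by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.285). For this shift, 2 explanations other than genotype were tested. With the slow fibre score as a covariate, the median log2 fold change kept a ratio of 0.978 to its reported value. The bootstrap 95% interval over the 15 members was 0.768 to 1.10, which does not cover spread between libraries. The score was 4.61, 6.77 and 4.75 in Igf2 cKO replicates 1 to 3 and 5.57 to 5.81 in controls. As it hardly tracks genotype, the covariate could move the genotype effect little, and the ratio alone cannot decide on fibre makeup. The list mean was higher in each Igf2 cKO library than in any control, while the score lay on both sides. This argues against a shift of that score as the source, and other aspects of fibre makeup were not tested. Time of day stays open. A set of 10 clock genes outside the list, fixed beforehand, had a median absolute log2 fold change of 0.11 (bootstrap interval 0.049 to 0.347). Of these, 2 (Per2 at 0.90 and Nr1d1 at -0.43) had an unadjusted p under 0.05 in edgeR. The set does not hold all clock genes tested. Nfil3 (1.38), Cry1 (0.35) and Bhlhe40 (-0.58), in neither the set nor the glucocorticoid list, also had an unadjusted p under 0.05. A direct effect of Igf2 loss, a difference in circulating hormone or handling stress, and a difference in food intake may each underlie the list, and none of these is weighed here.

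Igf2 itself was not called lower. The lower bound of its 95% interval, -0.889, lies above -1, so a 2-fold loss of the count is outside the interval. The interval is not adjusted for the number of genes tested, while a call is. Whether a 2-fold loss would have been called at the counts of Igf2 was not tested. Too few counts therefore stays open as a reason for the missing call. The bound of the interval concerns the count summed over the gene in whole tissue. Loss of the floxed exon in muscle fibres could leave that count in place, a candidate explanation that the deposited values cannot test.

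The real split of the 6 libraries gave 37 calls and the highest of the other splits 1. With 10 splits, the real one included (1 split reached the real count), they are too few for a share under 0.05.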
